A study of Mus musculus with 16 samples.

How the data were processed

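RNA abundance was measured by RNA sequencing of polyadenylated RNA in 16 mouse libraries, 2 for each of 2 genotypes at 0, 1, 3 and 5 h after 5 µM actinomycin D. Per the labels, lineage-depleted bone marrow was kept in culture with stem cell factor and thrombopoietin, haematopoietic stem cells were sorted at each time, ERCC spike-in RNA went into every RNA sample in the same amount, and Smart-seq2 libraries were built. The treatment protocol also names a sort at 4 h, which is not among the samples used here. Each deposited file holds counts, that is whole fragment counts per gene made with featureCounts 1.6.3 without regard to strand per the file headers, and the submitters' processing notes name STAR, DESeq2 and GRCm39. The deposited counts went into the fits without prior scaling. Every file has 55506 entries, of which 92 are ERCC spike-ins and 55414 are genes. Symbols and gene classes came from a GENCODE mouse table by gene identifier, with 52081 identifiers (94.0%) matched, and coordinates came from the file headers. The exonic length in the files, a different kind of value, was not used.

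Total counts per library ranged from 9142413 to 17274128 and ERCC counts from 3819 to 384621. Counts from polymerase chain reaction products without molecular identifiers are not independent molecules, so spreads and floors cover counting error only. CPM printed in the text are counts scaled to the gene counts of a library without TMM factors. TMM-scaled CPM were used to rank abundant genes and for the level required of named genes.

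Genotype and time came from the labels. Genes were tested where filterByExpr kept them over the 8 groups, which left 25081. Fits used edgeR 4.0.16 (quasi-likelihood F test, a mean for each of the 8 groups) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Genotypes were compared at each time and over the mean of the 4 times with TMM library factors, so these differences are relative to the other genes. Decay slopes were linear contrasts over 0, 1, 3 and 5 h with libraries scaled on ERCC counts, and their difference between genotypes was tested as an interaction. A half-life is the inverse of the falling slope, given only for falling genes or list medians. Errors on log2 values are standard errors worked back from the test, as the absolute log2 value over the square root of its F statistic. Errors on CPM are standard deviations of 2 files. All these tests, the gene lists, the splits and the naming of genes were fixed before the data were examined.

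Per gene list, camera of limma 3.58.1 with a preset correlation of 0.01 was run on log2 CPM (prior count 2) and adjusted over 25 lists. The lists hold RNA modification enzymes, HSC identity genes, immediate-early and AU-rich short-lived mRNAs, cytosolic ribosomal proteins, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, glycolysis, ribosome biogenesis, p53 targets, S phase, G2 and M phase, integrated stress response, unfolded protein response and heat shock, interferon response, RNA decay machinery, apoptosis regulators, fatty acid oxidation, long-lived reference mRNAs, and markers of neutrophils and monocytes, erythroid cells, megakaryocytes and platelets, B and T cells, mast cells and basophils, stroma, endothelium and macrophages, and sex-linked transcripts. The list tests for the mean of the times and for the slopes in the libraries labelled Nat10-deficient were added later. Camera asks whether a list moves apart from the other genes, and fry, run as an alternative, whether its genes move one way on balance.

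Named genes follow a rule. For each comparison these are the 8 with the largest change upward and the 8 downward among genes past the threshold with mean log2 CPM of at least 3, a symbol that is no clone or pseudogene name, and the same direction in both files of a group (at all 4 times for the mean, in both replicate numbers for slopes). Added to them are up to 4 members per list with the smallest p, Nat10, and the 10 genes with the highest mean CPM. The text gives a selection of these, and some genes that the rule picks are not reported here. Epx, Prg3, Cd34, Clec1a and Egr2 in the mean of the times are exceptions named after their values were seen. A gene with 0 counts in a group is given a bound with that group held at 3 counts, on the TMM scale.

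The pairs of files were checked with a chi-square over genes with at least 20 summed counts and with the spread beyond Poisson noise over genes with at least 2000. The 2 files of a group were then summed, for 0 h, the mean of the times and the slopes, in an added fit over 8 libraries. For 0 h and the slopes it held genotype, hours and their product, with 4 residual degrees of freedom, and for the mean of the times genotype and each time, with 3. The median biological coefficient of variation was 0.136 from the pairs and 0.983 from the summed libraries. The former holds the spread between files of a group, and the latter includes departures from the fitted straight lines. Neither measures the spread between sorted samples alone.

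The steps were tested on simulated data with 25081 genes, 200 of them changed, 50 at each size. At 0 h the fit of separate files found 76%, 98%, 100% and 100% of 1.25-, 1.5-, 2- and 4-fold changes and called 8 unchanged genes. For the mean of the times it found 94%, 100%, 100% and 100% and called 13, and DESeq2 1.42.0 found 88%, 100%, 100% and 100% and called 2. For slope differences of 0.1, 0.2, 0.4 and 0.8 it found 70%, 92%, 100% and 100% and called 6. Both genotypes were drawn from 1 profile per time with the spread between files of a group. Spike-ins were drawn at an equal share of every library, unlike the real ones. These rates of separate files therefore describe noise between files under even scaling, not the spread between sorted samples. With files summed, 0%, 4%, 6% and 80% of mean changes were found with 20 unchanged genes called, and 0%, 0%, 0% and 18% of slope differences with 3 called. Among 21 simulated lists of 40 genes the raised one had an adjusted p = 1.2e-110 and 0 of 20 unchanged lists passed. Genes were drawn independently, so correlation within a list was not simulated. The chi-square per degree of freedom was 1.00 for Poisson draws and 10.8 with 10% extra spread.

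Alternatives were RLE, ERCC, TMM and long-lived mRNA library scaling, no filter and a filter at mean log2 CPM of 3, DESeq2, a replicate block, a fit of the 4 libraries of a time alone, hours as a linear covariate, slopes without the first or the last time, an estimated correlation and fry for the lists, and each library left out in turn. Summed files, immunoglobulin genes left out, and 0 and 1 h alone were added after the data had been seen. Plasma cell markers (11 measured) and markers of secretory cells in general (8) were listed after the immunoglobulin share had been seen. Replicate numbers did not pair the libraries: over 28 correlations of residuals between groups the values lay between -0.011 and 0.033. Genotype labels were also swapped within times in 100 splits, and in 8 swaps that keep the files of a group together. Tables and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.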

Results

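RNA was sequenced from mouse blood-forming cells at 0, 1, 3 and 5 h after transcription was blocked with actinomycin D, an inhibitor of RNA synthesis. The fall of an mRNA over time was read as its decay, although each time is a separate sort whose mix of cells can differ. Per the labels, the cells were long-term haematopoietic stem cells (LT-HSCs) from bone marrow, either wild type (WT) or deficient in Nat10, the enzyme that places the acetyl mark ac4C on cytidines in RNA. The sample titles name 32D, a myeloid progenitor cell line, instead, and the sources used here do not settle which is meant. The 16 libraries form 8 groups of 2, one for each genotype and time. Total counts in the pairs of WT libraries were 13633973 and 12383302 at 0 h, 13157591 and 10051164 at 1 h, 9702619 and 9142413 at 3 h, and 14000072 and 11288586 at 5 h. Pairs of libraries labelled Nat10-deficient held 16865889 and 17274128 counts at 0 h, 14730106 and 14703917 at 1 h, 13516675 and 14067540 at 3 h, and 14502167 and 15401361 at 5 h.

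Averaged over all libraries, antibody transcripts ranked highest. Igkc, Igha, Ighm, Jchain and Ighg2b, which encode antibody chains, led the 10 genes with the highest mean under TMM scaling. The elongation factor gene Eef1a1, Gm10800, ENSMUSG00000119584, the myeloperoxidase gene Mpo and the mitochondrial mt-Co1 followed. ENSMUSG00000119584 had no symbol in the annotation used. The order differed between groups: Eef1a1 stood at 12793 CPM in WT at 0 h, above Ighm at 6310, and at 20712 in the libraries labelled Nat10-deficient at 5 h, below Igkc alone of these antibody genes. Immunoglobulin genes took 3.93% of gene counts in WT at 0 h, 27.9% at 1 h, 55.1% at 3 h and 66.5% at 5 h. In the libraries labelled Nat10-deficient the shares were 6.98%, 9.80%, 27.4% and 4.32%. The 2 files of a group differed in this share by at most 0.323 percentage points, while the 16 libraries ranged from 3.91% to 66.7%. ERCC spike-ins, synthetic RNAs added in equal amounts per the labels, made up 1.79% to 2.92% of counts in WT and 0.0221% to 0.129% in the libraries labelled Nat10-deficient.

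Each pair of files differed by little more than counting noise, so the tests below measure the spread between files of a group and not the spread between separately sorted samples. Over genes with at least 20 summed counts, the chi-square per degree of freedom within pairs was 1.43 to 1.81, against 47.9 to 256 between neighbouring times of a genotype. The labels call the replicates biological, yet in all 8 groups the headers of both files name the same alignment. The comparisons at 0 h, for the mean of the times and of the slopes were therefore also run with the 2 files of each group summed, which leaves 4 residual degrees of freedom in a fit of straight lines over the times for 0 h and the slopes. For the mean it leaves 3 in a fit with each time on its own. No such run was made at 1, 3 or 5 h.

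**Figure D1:**
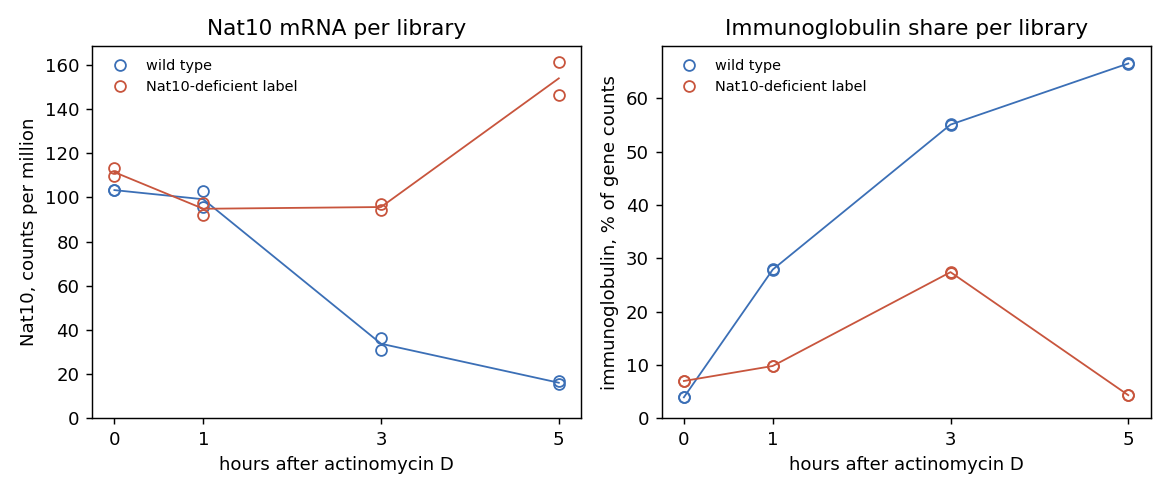
Nat10 CPM (left) and the immunoglobulin share of gene counts in percent (right) in each of the 16 libraries against hours after actinomycin D, with lines through the means of the 2 libraries per group. Nat10 lay at 103 and 103 CPM in WT and at 110 and 113 in the libraries labelled Nat10-deficient at 0 h.

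Nat10 mRNA was higher in the libraries labelled Nat10-deficient at 0, 3 and 5 h and slightly lower at 1 h. Nat10 (ENSMUSG00000027185, chromosome 2, 103551601 to 103591615, GRCm39) stood at 103 ± 0.042 CPM, counts scaled to the gene counts of the library, in WT and 111 ± 2.5 in the libraries labelled Nat10-deficient at 0 h (mean ± SD, n = 2 files). Relative to all genes it was higher by log2 0.33 ± 0.049 (SE, adjusted p = 9.69e-10) at 0 h, lower by log2 fold change -0.12 ± 0.053 (adjusted p = 0.0421) at 1 h, and higher by 1.21 ± 0.069 at 3 h and 1.96 ± 0.073 at 5 h. The difference of 0.33 is smaller than the shift of -0.37 that scaling the libraries on long-lived mRNAs gives all genes at 0 h, and it was -0.01 in the fit of summed files. Counts over the whole gene show neither whether an exon was removed nor whether the labels of the genotypes were exchanged. An exchange would turn every direction below. The labels are used here as given, and every direction below is between libraries labelled Nat10-deficient and libraries labelled WT.

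The comparison at 0 h asks which mRNAs differed before transcription was blocked. Genes that mark stem cells were lower in the libraries labelled Nat10-deficient, and genes of cell division, of mitochondrial respiration and of mast cells and basophils were higher. Procr, the endothelial protein C receptor used to sort HSCs, differed by log2 fold change -1.89 ± 0.055, and Vwf, von Willebrand factor, by -1.84 ± 0.050. Of 40 HSC identity genes 35 were lower, 2 higher and 3 not past the threshold, and the list's median was -1.25.

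Of 42 immediate-early and AU-rich short-lived mRNAs 26 were lower and 10 higher (median -0.38), and the list did not pass camera with summed files (adjusted p = 0.199). Nr4a1, a nuclear receptor gene induced within minutes of stimulation, differed by -1.99 ± 0.026, Egr2 by -2.17 ± 0.034, the anti-proliferative gene Btg2 by -1.61 ± 0.021 and Fos by -1.50 ± 0.022. The co-chaperone gene Dnajb1 also ran low, by -1.52 ± 0.023, within a list of unfolded protein response and heat shock genes of which 22 of 25 were higher (median 0.59). Its members Calr and Sdf2l1, which help fold proteins in the endoplasmic reticulum, were higher by 1.03 ± 0.023 and 1.42 ± 0.036.

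Cell cycle genes were higher in the libraries labelled Nat10-deficient: 27 of 30 S phase genes (median 0.67) and 29 of 30 G2 and M phase genes (median 0.77). Mcm5 and Mcm6, parts of the replicative helicase, differed by 0.91 ± 0.030 and 0.76 ± 0.026, Nusap1, a spindle protein gene, by 1.33 ± 0.052, and Ube2c, an enzyme of mitotic exit, by 1.09 ± 0.052. Of 38 nuclear-encoded genes of oxidative phosphorylation 36 were higher and none of the 38 lower (median 0.54), among them Atp5b of the ATP synthase (0.60 ± 0.019) and Sdhc (0.94 ± 0.046). Of 13 mitochondrially encoded mRNAs 12 were higher (median 0.89, adjusted p = 0.110 with an estimated correlation), with mt-Nd2 at 1.24 ± 0.036. Ribosome biogenesis genes were higher in 33 of 40 cases (median 0.42), including Ncl (0.60 ± 0.021) and Pes1 (0.73 ± 0.044). Of 50 cytosolic ribosomal protein genes 44 were higher (median 0.23, adjusted p = 0.264 with an estimated correlation), as Rps2 was (0.39 ± 0.018), although scaling on long-lived mRNAs turned that median to -0.14 with 33 lower and 6 higher. Enzymes of ac4C and other RNA modifications, among them the methyltransferase gene Nop2 (0.99 ± 0.035), were higher in 14 of 20 cases (median 0.39). Scaling on long-lived mRNAs lowers all genes by nearly as much as this median and that of ribosome biogenesis.

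Marker genes of other blood lineages differed as well. Mast cell and basophil markers were higher in 17 of 19 cases and lower in 2, with a median of 1.86, or 1.76 with genes absent from a group held at a 3-count floor. Cpa3 and Mcpt8, proteases of mast cells and basophils, were higher by 1.86 ± 0.056 and 2.33 ± 0.072, whereas Gata2, a transcription factor gene that HSCs share, was lower by -1.07 ± 0.040. B and T lymphoid markers were higher in 17 of 25 cases and lower in 2 (median 1.04, or 0.94 at the floor), with Dntt of early lymphoid cells at 2.45 ± 0.12 and the interleukin 7 receptor gene Il7r at 4.01 ± 0.25. The immunoglobulin share was 6.98% against 3.93% in these libraries. Erythroid markers were higher in 14 of 19 cases (median 0.71), with Car1 at 1.05 ± 0.022, and neutrophil and monocyte markers in 12 of 19 (median 0.54), with Mpo at 1.05 ± 0.017. Neither list was called with an estimated correlation (adjusted p = 0.0556 and adjusted p = 0.199). Megakaryocyte and platelet markers split into 8 higher and 8 lower of 19, and Mmrn1, a platelet protein gene also found in HSCs, was lower by -1.94 ± 0.038.

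Of the other lists, the integrated stress response (16 higher, 2 lower of 22, median 0.36) and the long-lived reference mRNAs (34 higher of 38, median 0.39) passed camera, and the others below did not. Glycolysis (15 higher, 4 lower, adjusted p = 0.175) had a median of 0.31 but a mean of -0.13. p53 targets (12 higher, 10 lower, adjusted p = 0.254) had a median of 0.03 and a mean of -0.12. Interferon response (15 higher, 9 lower, adjusted p = 0.900), RNA decay machinery (22 higher, 6 lower, adjusted p = 0.0832), apoptosis regulators (15 higher, 5 lower, adjusted p = 0.145), fatty acid oxidation (17 higher, 5 lower, adjusted p = 0.0837), markers of stroma, endothelium and macrophages (9 higher, 6 lower, adjusted p = 0.900) and megakaryocyte markers (adjusted p = 0.221) did not pass. Of the sex-linked transcripts only 2 of 6 had enough counts, and 1 of them was lower. For integrated stress response, interferon response, RNA decay, apoptosis, fatty acid oxidation, glycolysis and p53 targets the sign of the median turned under scaling on long-lived mRNAs.

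In all, 9037 genes were higher and 6082 lower at 0 h of 25081 tested. Adjusted over the list alone, the counts past the threshold were those over all genes except for 45 ribosomal protein, 37 ribosome biogenesis and 29 RNA decay genes. Camera with a preset correlation called 16 of 25 lists. With an estimated correlation 12 of them held, and the ribosomal protein, mitochondrially encoded, neutrophil and monocyte, and erythroid lists did not. Scaling on long-lived mRNAs gave 5615 higher and 9562 lower genes, and scaling on ERCC counts, which shifts all genes by 6.13, gave 21902 higher and 2 lower. With the files of each group summed, edgeR called 0 genes at 0 h, with 1240 at an unadjusted p under 0.05, and 14 of the 16 lists remained, without the immediate-early list and the integrated stress response (adjusted p = 0.129).

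**Figure D2:**
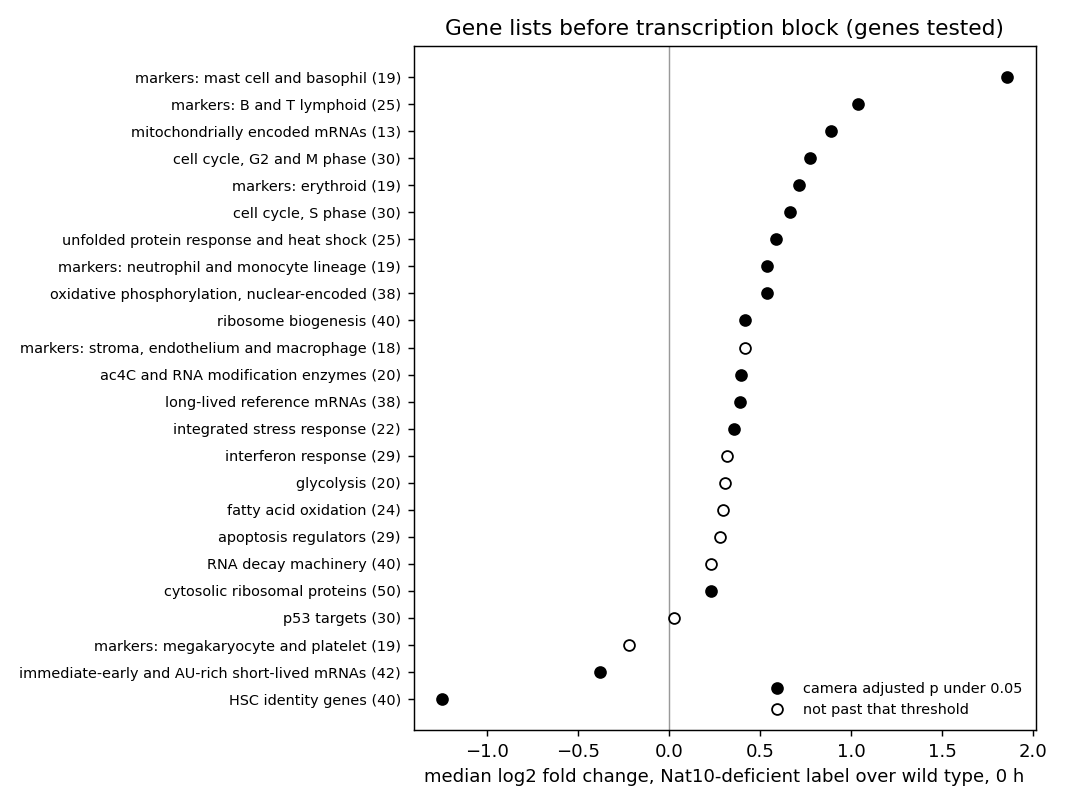
Median log2 difference of libraries labelled Nat10-deficient from WT at 0 h for each gene list but the sex-linked transcripts, on TMM scaling. Filled points mark lists with a camera adjusted p under 0.05, and open points mark the others. The HSC identity genes have a median of -1.25 and the mast cell and basophil markers one of 1.86.

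The genes that the naming rule picked for the largest differences at 0 h were mostly immunoglobulin genes, 8 of 8 among the higher and 4 of 8 among the lower. Igkv4-90 had 551 counts in the libraries labelled Nat10-deficient and 0 in WT, at least 160-fold higher with WT held at 3 counts over the group. Igkv4-80 and Ighv3-1 were lower, by -4.73 ± 0.092 and -5.53 ± 0.11. Reads of variable segments can be shared between near-identical family members. The other genes lower by the most were Matn4, an extracellular matrix protein gene (46.5 ± 2.4 CPM in WT, 1.29 ± 0.022 in the libraries labelled Nat10-deficient), Fhdc1, which regulates actin and microtubules, Sult1a1, a sulfotransferase gene, and Siglech, a dendritic cell receptor gene with 40 counts in WT and 0 in the other genotype, at least 15.3-fold lower.

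At 1, 3 and 5 h the comparison asks what was left in each genotype after transcription stopped. Stab2, a scavenger receptor gene, was higher in the libraries labelled Nat10-deficient at 1 h (29.8 ± 2.7 against 1.43 ± 0.15 CPM), as was Ddias, a DNA damage survival gene (22.6 ± 0.068 against 0.530 ± 0.025 CPM). At 3 h Cdyl2, a chromodomain protein gene, was higher by 4.99 ± 0.38, and Bhlha15, a transcription factor gene of secretory cells that plasma cells express, was lower by -4.20 ± 0.18. At 5 h Siglecf, a receptor gene of eosinophils, was at least 54.5-fold higher and the kinase-like gene Adck1 at least 65.4-fold higher, both with 0 counts in WT. The lymphocyte adhesion gene Cd2 was at least 363-fold lower and Igkv8-34 at least 2316-fold lower, both with 0 counts in the libraries labelled Nat10-deficient. WT at 5 h stands apart in such losses, with 234 of the 340 cases over the 8 groups of a gene at 0 counts in a file despite at least 10 CPM at another time of the genotype. Igkv4-80 was lower by -6.83 ± 0.059 at 1 h and -5.64 ± 0.048 at 3 h.

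The immunoglobulin share was higher in WT at each of these times, 66.5% against 4.32% at 5 h, and immunoglobulin segments made up 8 of the 8 most reduced named genes at 1 h, 7 of 8 at 3 h and 4 of 8 at 5 h. Over all genes, 8116 were higher and 7981 lower at 1 h, 7632 and 9282 at 3 h, and 8569 and 7540 at 5 h. Scaling on long-lived mRNAs gave 4080 higher and 12794 lower at 1 h, 2721 and 15252 at 3 h, and 6156 and 9543 at 5 h. With ERCC scaling 21190 were higher and 13 lower at 1 h, 20265 and 68 at 3 h, and 21114 and 174 at 5 h.

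Averaged over the 4 times, the comparison asks how the genotypes differed on balance, and it does not say that a difference held at each time. The cell cycle, oxidative phosphorylation and erythroid lists were higher in the libraries labelled Nat10-deficient, and the HSC identity and immediate-early lists were lower. Chosen after their values were seen, because they also passed with the files summed, were Epx and Prg3, granule protein genes of eosinophils (2.32 ± 0.018 and 2.35 ± 0.038), Cd34, a surface marker gene of progenitors (2.29 ± 0.030), Clec1a, a lectin gene of endothelium (-2.70 ± 0.072), and Egr2 (-1.88 ± 0.037). Car1, carbonic anhydrase of erythroid cells, and Aqp1, a water channel gene of red cells, were higher by 1.68 ± 0.011 and 1.64 ± 0.015 and passed with summed files too (adjusted p = 0.0365 and adjusted p = 0.0411). Igkv4-80 and Ighv3-1 were lower by -6.23 ± 0.033 and -6.70 ± 0.042, again with summed files passing (adjusted p = 0.00568 and adjusted p = 0.0177). In simulated data the summed fit for the mean called 20 unchanged genes, so passing it is weak support for a gene.

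On average over the times, HSC identity genes were lower in the libraries labelled Nat10-deficient, with 31 of 40 lower and 3 higher (median -0.90; -1.25, -1.19, -0.04 and -0.74 at 0, 1, 3 and 5 h, the last -1.01 at the floor), including Procr (-1.75 ± 0.034) and Ly6a, the Sca-1 gene (-1.75 ± 0.030). All 30 S phase and all 30 G2 and M phase genes were higher (medians 1.02 and 0.98), with Mcm5 at 1.28 ± 0.017, the centromere histone gene Cenpa at 1.53 ± 0.024 and Ube2c at 1.52 ± 0.029. Oxidative phosphorylation genes were higher in 37 of 38 cases (median 0.80), as shown by Uqcrc1 (1.01 ± 0.013) and Atp5b (0.94 ± 0.0096). Ribosome biogenesis genes were higher in 39 of 40 (median 0.70), as shown by Npm1 (1.04 ± 0.014) and Nop2 (1.17 ± 0.023), which the list of RNA modification enzymes holds (20 of 20 higher, median 0.77). Immediate-early genes were lower in 34 of 42 cases (median -0.71), Fos by -1.37 ± 0.017 and Btg2 by -1.15 ± 0.014. Ribosomal protein genes were higher in 47 of 50 cases (median 0.47). Their median was -0.12 under scaling on long-lived mRNAs, which shifts all genes by -0.58, and camera gave adjusted p = 0.0628 with an estimated correlation.

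B and T lymphoid markers were lower on average in 15 of 25 cases and higher in 2 (median -0.98, or -0.91 at the floor), with list medians of 1.04 at 0 h, -1.08 at 1 h, -1.31 at 3 h and -3.39 at 5 h. Cd79a, part of the B cell receptor, was lower by -1.94 ± 0.031 and Xbp1, a transcription factor gene needed by plasma cells, by -1.78 ± 0.013, beside the lower immunoglobulin share after 0 h. Mast cell and basophil markers were higher on average in 15 of 19 cases (median 1.08), with medians of 1.86, -0.24, 2.68 and 0.93 at 0, 1, 3 and 5 h (1.76, -0.24, 1.82 and 0.55 at the floor), Cpa3 by 1.90 ± 0.030, and erythroid markers in 15 of 19 (median 1.04). Megakaryocyte markers were higher in 13 of 19 cases (median 0.59, or 0.34 at the floor, adjusted p = 0.0965), Pf4 by 1.81 ± 0.038, while Mmrn1 was lower by -1.78 ± 0.025. The unfolded protein response and heat shock list had 10 higher and 13 lower members (adjusted p = 0.4). Adjusted over the list alone, the counts past the threshold were those over all genes except for 39 immediate-early, 48 ribosomal protein, 23 interferon response, 18 erythroid and 38 long-lived genes.

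The mean of the 4 times gave 7925 higher and 5421 lower genes. DESeq2 gave 6619 higher and 7540 lower, scaling on long-lived mRNAs 3373 and 9799, and ERCC scaling 17940 and 2. With summed files 8 genes were higher and 9 lower, and all 17 were among those called from the separate files.

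Decay in WT asks how fast each mRNA was lost when transcription had stopped, measured as the slope of log2 counts per ERCC count against hours. Immunoglobulin counts per ERCC count were 12.1 times as high at 5 h as at 0 h in WT although transcription was blocked. Slopes and half-lives are therefore apparent ones that also hold changes in the mix of RNA between the sorted samples. Among the lists, the immediate-early and HSC identity mRNAs had the 2 lowest median slopes. Egr3 fell by 2.17 ± 0.028 per h on the log2 scale, a half-life of 0.460 h, and Nr4a1 by 1.80 ± 0.013, a half-life of 0.555 h. The HSC regulators Gata2 and Meis1 had half-lives of 0.743 and 0.772 h, the interferon regulator Irf1 one of 0.860 h, and the heat shock gene Dnajb1 one of 0.865 h. Rps6 and Rpl3, of the small and large ribosomal subunits, had half-lives of 3.24 and 3.32 h.

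All 42 immediate-early and AU-rich mRNAs fell in WT, with a median slope of -0.93 and a half-life of 1.08 h at that median, and 39 of 40 HSC identity genes fell (median -0.82, 1.22 h). All 40 genes of the RNA decay machinery fell (median -0.48, 2.10 h), and so did all 20 RNA modification enzymes (median -0.53, 1.90 h), Ythdf2, which reads N6-methyladenosine, among them (half-life 1.03 h). All 40 ribosome biogenesis genes fell (2.23 h at the median, 1.32 h for Nop58), as did 23 of 24 fatty acid oxidation genes (2.24 h at the median, 1.15 h for Cpt1a, the carnitine palmitoyltransferase gene). Each of the 50 ribosomal protein mRNAs fell, with the list's half-life at 3.88 h, and 37 of 38 oxidative phosphorylation mRNAs fell (3.69 h, Uqcrc1 2.56 h). Relative to the shift of 0.39 that TMM scaling gave all slopes, the ribosomal protein, oxidative phosphorylation and long-lived reference lists turned to medians of 0.14, 0.12 and 0.14 under TMM.

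B and T lymphoid markers rose in WT in 15 of 25 cases and fell in 8 (median slope 0.27, or 0.13 at the floor). Cd79a rose by 0.82 ± 0.011 per h, from 21.1 ± 0.49 CPM at 0 h to 583 ± 18 at 5 h, while the immunoglobulin share rose from 3.93% to 66.5%. All 8 of the most rising named genes in WT were immunoglobulin genes. The unfolded protein response and heat shock list had 9 rising and 14 falling members (adjusted p = 0.342), and the neutrophil and monocyte list 7 and 10 (adjusted p = 0.0605).

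The other lists fell in WT, with 27 of 30 p53 targets, all 30 S phase and all 30 G2 and M phase genes, 19 of 20 glycolysis genes, 25 of 29 interferon response genes, 27 of 29 apoptosis regulators, 18 of 19 megakaryocyte markers and 36 of 38 long-lived reference mRNAs past the threshold. Camera called these 8 lists, and it gave adjusted p = 0.0649 for the integrated stress response (18 of 22 falling), adjusted p = 0.121 for mitochondrially encoded mRNAs (11 of 13), adjusted p = 0.0949 for erythroid (16 of 19), adjusted p = 0.854 for mast cell (10 of 19), adjusted p = 0.952 for stromal (12 of 18) and adjusted p = 0.854 for sex-linked genes (1 of 2). Camera named ribosomal protein, oxidative phosphorylation and long-lived mRNAs as falling although their medians lie 0.11, 0.09 and 0.11 above that of all genes. Adjusted over the list alone, counts were those over all genes except for 20 glycolysis, 28 interferon response and 10 mast cell genes. Of the 17 lists called, 4 held with an estimated correlation: immediate-early, HSC identity, RNA decay machinery and lymphoid markers. The others had an adjusted p = 0.0547 (ribosome biogenesis, S phase and apoptosis), adjusted p = 0.0597 (G2 and M phase, RNA modification and fatty acid oxidation), adjusted p = 0.0873 (interferon), adjusted p = 0.0927 (glycolysis and p53), adjusted p = 0.116 (oxidative phosphorylation), adjusted p = 0.137 (megakaryocyte) and adjusted p = 0.224 (ribosomal protein and long-lived mRNAs).

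In WT 14398 genes fell and 2794 rose, and the median half-life of the falling genes was 1.91 h. The median slope of all genes was -0.36 over the 4 times and -0.83 over 0 and 1 h alone, so half-lives depend on the times used. With TMM scaling 7825 fell and 7055 rose, with RLE scaling 6904 and 7896, and with long-lived mRNAs 11119 and 4686. Summed files gave 6685 falling and 212 rising genes, 6747 of them among the main calls.

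In the libraries labelled Nat10-deficient the immediate-early and HSC identity lists also had the 2 lowest median slopes. Nr4a1 fell by 2.71 ± 0.018 per h, a half-life of 0.370 h, and half-lives were 0.748 h for Meis1, 0.770 h for the HSC transcription factor gene Hlf, 0.804 h for Gata2, 0.740 h for Irf1 and 0.979 h for Ythdf2. Uqcrb of the respiratory chain had one of 2.46 h, and Gnl3, a nucleolar GTPase gene, one of 1.30 h. All 42 immediate-early and all 40 HSC identity genes fell, with half-lives of 0.827 and 1.19 h at the list medians (adjusted p = 0.0615 for both with an estimated correlation). Lymphoid markers fell in 23 of 25 cases, where WT had 8. Adjusted over the list alone, counts differed from those over all genes only for 17 markers of stroma, endothelium and macrophages. The basophil protease gene Prss34 rose by 0.20 ± 0.0068 per h.

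Over all genes 17893 fell and 800 rose in the libraries labelled Nat10-deficient, with a median half-life of the falling genes of 1.74 h and a median slope of -0.48, or -1.33 over 0 and 1 h alone. TMM scaling, which shifts all slopes by 0.49, gave 7984 falling and 7282 rising genes, RLE scaling 7040 and 8390, and long-lived mRNAs 13114 and 2929. Summed files gave 8888 falling and 3 rising genes, and 8822 of these calls were shared.

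**Figure D3:**
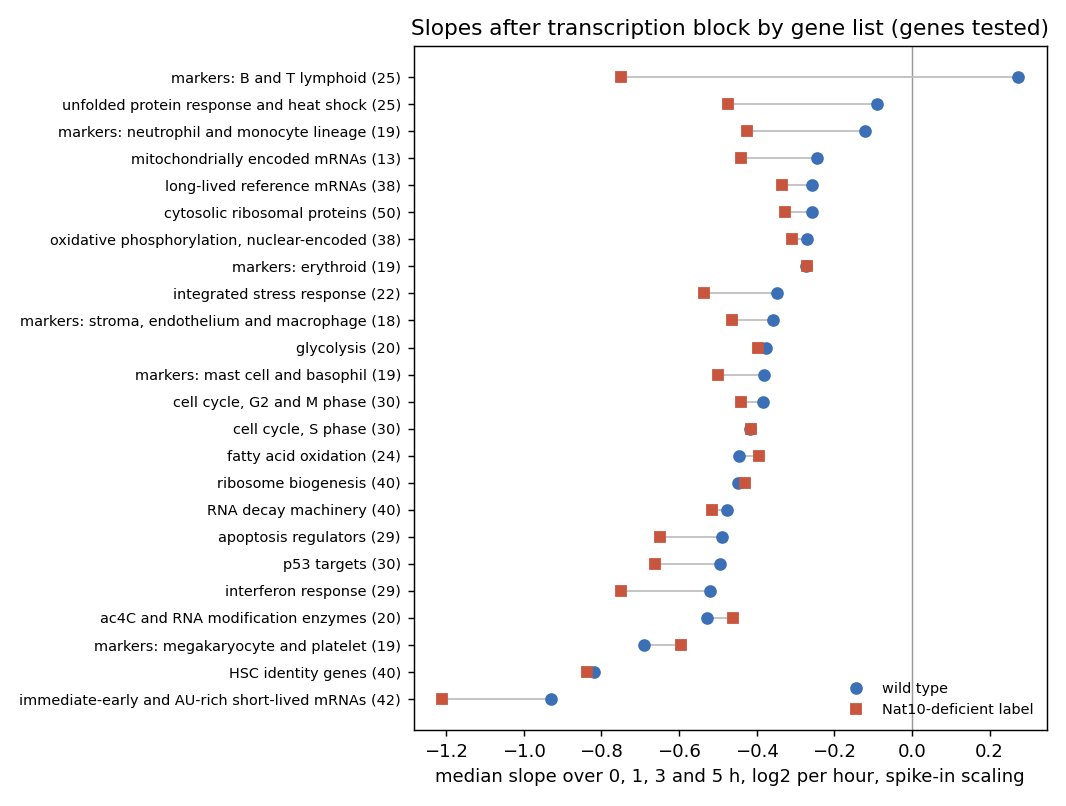
Median decay slope of each gene list but the sex-linked transcripts in log2 per h on ERCC scaling, in WT and in libraries labelled Nat10-deficient. The immediate-early list lies lowest in WT at -0.93, and the lymphoid markers lie at 0.27 in WT and -0.75 in the libraries labelled Nat10-deficient.

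The difference between the slopes asks whether mRNA stability differed where Nat10 is labelled as lacking. A negative value is a lower slope in the libraries labelled Nat10-deficient, which is faster loss only for mRNAs that fell in both genotypes. In WT 15 of 25 lymphoid markers, 9 of 25 unfolded protein response and heat shock genes and 7 of 19 neutrophil and monocyte markers rose. Camera called 9 lists, of which the B and T lymphoid markers alone held with an estimated correlation (adjusted p = 0.0215). These markers were lower in 23 of 25 cases and higher in 0 (median -0.999, or -0.77 at the floor), Cd79a by -1.19 ± 0.018 and Il7r by -1.62 ± 0.051. The unfolded protein response and heat shock list was lower in 18 of 25 cases (median -0.42, adjusted p = 0.467 with an estimated correlation), Xbp1 by -1.03 ± 0.011 and Herpud1, which helps clear misfolded proteins, by -0.90 ± 0.012. In WT Herpud1 stood at 206 ± 5.5 CPM at 0 h and 587 ± 3.2 at 3 h, times at which the immunoglobulin share was 3.93% and 55.1%.

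Immediate-early and AU-rich mRNAs had lower slopes in 34 of 42 cases and higher ones in 2 (median -0.33, adjusted p = 0.0717 with an estimated correlation and 0.786 upward over 0 and 1 h alone), Fosb by -0.62 ± 0.011, the NF-kappaB inhibitor gene Nfkbia by -0.56 ± 0.012 and the cytokine signalling inhibitor gene Socs3 by -0.59 ± 0.016. Neutrophil and monocyte markers were lower in 18 of 19 cases (median -0.39), the monocyte surface gene Ly6c2 by -0.71 ± 0.010. Over 0 and 1 h alone, however, camera called this list as higher (adjusted p = 0.00998). Interferon response genes were lower in 23 of 29 cases (median -0.23), the nucleic acid sensor gene Zbp1 by -0.90 ± 0.030, and mitochondrially encoded mRNAs in 10 of 13 (median -0.18), mt-Nd5 by -0.26 ± 0.011. Over 0 and 1 h alone neither list passed (adjusted p = 0.0887 and adjusted p = 0.3). With an estimated correlation the neutrophil, interferon and mitochondrial lists each had an adjusted p = 0.402. Ribosome biogenesis (17 higher, 9 lower of 40), RNA modification enzymes (9 higher, 5 lower of 20) and fatty acid oxidation (10 higher, 5 lower of 24) were called as higher with medians of 0.02, 0.02 and 0.0056. They were not called with an estimated correlation (adjusted p = 0.446, adjusted p = 0.467 and adjusted p = 0.446) or with summed files (adjusted p = 0.0576, adjusted p = 0.0971 and adjusted p = 0.0971). Nop58 and Cpt1a were higher by 0.22 ± 0.011 and 0.27 ± 0.019. The slope of Nat10 itself was -0.62 in WT and -0.33 in the libraries labelled Nat10-deficient, a difference of 0.29 ± 0.018 (adjusted p = 3.52e-58, but 0.937 with summed files).

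HSC identity genes split into 14 higher and 13 lower of 40 (median -0.03, camera upward, adjusted p = 0.457), with the transcription factor gene Lmo2 higher by 0.45 ± 0.021 and Ly6a lower by -1.07 ± 0.020. With slopes from 0 and 1 h alone, Lmo2, Cpt1a and Nat10 turned to -0.18, -0.17 and -0.86. Ribosomal protein mRNAs (38 of 50 lower, adjusted p = 0.0624), apoptosis regulators (17 of 29 lower, adjusted p = 0.0624), p53 targets (20 of 30 lower, adjusted p = 0.112), long-lived mRNAs (26 of 38 lower, adjusted p = 0.0801), oxidative phosphorylation (19 of 38 lower, adjusted p = 0.846), glycolysis (12 of 20 lower, adjusted p = 0.685), RNA decay machinery (22 of 40 lower, adjusted p = 0.796), the integrated stress response (12 of 22 lower, adjusted p = 0.566), stromal markers (8 of 18 lower, adjusted p = 0.693), mast cell markers (6 of 19 lower, adjusted p = 0.693) and sex-linked transcripts (1 of 2 lower, adjusted p = 0.483) did not pass camera. Nor did S phase (12 of 30 lower, adjusted p = 0.6), G2 and M phase (14 of 30 lower, adjusted p = 0.970), erythroid (8 of 19 higher, adjusted p = 0.0959) or megakaryocyte genes (10 of 19 higher, adjusted p = 0.0624). Over 0 and 1 h alone camera called the S phase (adjusted p = 0.0120) and erythroid lists (adjusted p = 0.00395) as higher and the mast cell list as lower (adjusted p = 0.00560).

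In total 3928 slopes were higher and 8054 lower, but with hours as a linear covariate 536 were higher and 1800 lower. Over 0, 1 and 3 h 2548 were higher and 10896 lower, and over 1, 3 and 5 h 6408 and 6785. TMM scaling gave 6140 and 6078, RLE scaling 6159 and 6065, and long-lived mRNAs 5561 and 6542. TMM and RLE centre the slopes, which by itself evens out higher and lower ones. With summed files 10 were higher and 60 lower, 62 of them shared with the main calls, and 25 of the 60 were immunoglobulin genes. Il7r (-1.36 ± 0.34 in that fit, adjusted p = 0.0461), Bcl2l11, which promotes apoptosis (-0.85 ± 0.20, adjusted p = 0.0365), the platelet gene Treml1 (adjusted p = 0.00195) and Kdelc2 (adjusted p = 0.0459) were among those passing with summed files. Treml1 had 0 counts in WT at 3 and 5 h and Kdelc2 at 5 h, so their fitted slopes are no bound. Adjusted over the list alone, counts past the threshold differed from those over all genes only for 41 ribosomal protein, 27 ribosome biogenesis, 24 S phase and 30 RNA decay genes. Of the 9 lists, the lymphoid, immediate-early, protein folding and neutrophil lists passed with summed files.

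Among 8281 genes with mean log2 CPM of at least 3 that fell in both genotypes, the median half-life was 2.16 h in WT and 1.97 h in the libraries labelled Nat10-deficient, and 5055 (61.0%) were shorter in the latter. Of these genes 74.0% had the lower slope in the latter over 0 and 1 h alone, 74.0% over 0, 1 and 3 h, and 49.8% over 1, 3 and 5 h, so the shorter half-lives depend on the 0 h libraries. Across 8778 genes, which are not independent replicates, the slopes of the genotypes had Pearson's r of 0.420 and Spearman's rho of 0.489.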

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

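The tests of the pairs of files, of immunoglobulin and plasma cell counts, of summed files, without immunoglobulin genes and over 0 and 1 h alone were chosen after the result was seen, as was the use of TMM scaling to test the spike-in scaling.

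The decay slope differed between genotypes, by a test of the difference itself, in 11982 genes, and in 2336 with hours as a linear covariate. Camera with a preset correlation called 9 gene lists, of which 1 held with an estimated correlation and 4 with summed files, with median differences of -0.999 for B and T lymphoid markers, -0.42 for the unfolded protein response and heat shock, -0.39 for neutrophil and monocyte markers, -0.33 for immediate-early mRNAs, -0.23 for the interferon response, -0.18 for mitochondrially encoded mRNAs, and 0.023, 0.022 and 0.0056 for RNA modification enzymes, ribosome biogenesis and fatty acid oxidation. The slope difference of Nat10 was 0.29 log2 per h, but it was -0.86 over 0 and 1 h alone and had an adjusted p = 0.937 with summed files.

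Against 11982 slope differences, 12218 were called under TMM in place of spike-in scaling, 10006 of them main calls in the same direction. With the spread between nearly identical files as the error, many calls follow under any scaling, so this count does not decide on spike-in scaling. The excess of lower slopes, 8054 against 3928 higher, became 6078 against 6140 under TMM, which centres the slopes. Leaving out immunoglobulin genes (11756 remained) cannot move slopes scaled on ERCC counts and decides nothing. Of the 100 splits that swap genotype labels within times, 8 gave as many genes, the highest of the others 18595, and of the 8 swaps that keep the files of a group together, too few for a share under 0.05, 8 did, the highest of the others 17948. The genotypes lie 5.54 log2 apart on the ERCC scale at the median gene, which a swap at some times carries into the slopes by design, so these splits do not decide on chance. With the 2 files of each group summed 62 calls remained, because the median SE went from 0.052 to 0.28 while the median absolute difference went from 0.36 to 0.32, and as that fit found 18% of simulated differences of 0.8, the lost calls decide nothing. Differences between the sorted samples that the files of a group do not measure and an effect of Nat10 on mRNA stability both stay open.

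The 2 files of each group differed little. A single library whose reads were divided at random over 2 files is argued against by the chi-square per degree of freedom. It was 1.43 at its lowest where such a division gives about 1. Small separate samples of cells that lose transcripts independently are argued against too: of 340 cases in which a gene of at least 10 CPM elsewhere had 0 counts in a file, 0% had 10 or more in the other file, the highest being 7. The spread beyond Poisson noise reached 1.80% at most, as 2 libraries from 1 sample of cells could give. These values do not tell that case from 1 library sequenced in 2 runs. No biological explanation was tested, since the design gives no group for this.

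The immunoglobulin share rose in WT from 3.93% at 0 h to 66.5% at 5 h. Loss of other mRNAs around a constant amount of immunoglobulin mRNA is argued against, since immunoglobulin counts per ERCC count were 12.1 times as high at 5 h as at 0 h and transcription was blocked. This holds only if the spike-in added per sorted cell was alike at both times, which the sources used here do not give. RNA of plasma cells is a candidate explanation: over the 8 summed libraries the share of 11 plasma cell markers among other counts rose with the immunoglobulin share (2 relations tested; Spearman's rho 0.976, exact two-sided permutation p = 0.000397, adjusted p = 0.000794; Pearson's r 0.988, exact permutation p = 4.96e-05, adjusted p = 9.92e-05, and 0.945 without WT at 5 and 3 h). In WT, Igkc went from 22612 to 331636 CPM of all gene counts, and Sdc1 went from 83.7 to 1652 and Cd79a from 22 to 1737 CPM of other counts. The 11 markers summed to 5238 CPM in WT at 5 h, so Cd79a and Sdc1 carried much of the relation. Cd79a is also in the B and T lymphoid list, so the relation does not tell plasma cells from B cells. The permutations treat the 8 libraries as exchangeable, although they are ordered in time within genotypes. However, 8 markers of secretory cells in general gave a similar relation (rho 0.952, exact permutation p = 0.00114). Their Pearson's r was 0.959, and 0.839 without WT at 5 and 3 h. Lineage depletion and the stem cell sort would also remove plasma cells. The markers per ERCC count were 3.34 times as high at 5 h as at 0 h, less than the immunoglobulin counts, and a difference between genotypes in these cells stays open, untested.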

How the results depend on the processing

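The tests with summed files and with 0 and 1 h only were chosen after the result was seen. Leaving out each of the 16 libraries in turn, the lone library of a group taken to vary like the others, gave 144 values of the 9 summary results, all of the same direction and within 1.5 times, but a nearly identical file stays in each group, so this says nothing about the spread between samples: 12581 to 15217 genes at 0 h, 13607 to 16144 at 1 h, 14647 to 16975 at 3 h, 13541 to 16132 at 5 h, 12705 to 13157 for the mean, 16352 to 17212 and 17886 to 18671 for the slopes in WT and in the libraries labelled Nat10-deficient, 10557 to 11906 for their difference, and 0.31 to 0.35 for Nat10 at 0 h. With a replicate block the counts were 14857, 15893, 16701, 15942, 13318, 17093, 18545 and 11968, and Nat10 was at 0.33. With mean log2 CPM of at least 3, where fewer genes were tested, they were 6540, 7015, 6710, 7377, 7614, 8673, 8763 and 6733. Summed files, which leave 8 libraries, gave 0 genes at 0 h (1240 at an unadjusted p under 0.05 by edgeR), 17 for the mean, 6897 and 8891 for the slopes and 70 for their difference, of which 0, 17, 6747, 8822 and 62 were among the main calls. Nat10 at 0 h was then -0.012, read from a straight line through 4 times. Hours as a linear covariate gave 2336 slope differences, with a median over all genes of -0.13 against -0.096 in the main fit. The covariate fit takes departures from straight lines into its error, which the main fit does not. How many of the lost calls this accounts for was not tested.

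The estimated correlation left 4 lists for the WT slope and 1 for the slope difference, fry called 24 for the slope difference, and summed files 4, all among the main 9. With 0 and 1 h only, the slope differences of Lmo2, Cpt1a and Nat10 reversed to -0.18, -0.17 and -0.86, the neutrophil and monocyte list was called as higher (adjusted p = 0.00998), the S phase, erythroid and mast cell lists were newly called, and 5169 of the main slope differences remained among 12759, with the cause not tested. Over 3003 values of single genes under these alternatives, 2920 stayed the same in direction and call, 80 lost the call and 3 reversed. Under the other library scalings the shift of all genes was subtracted first, so a reversal by scaling alone cannot show in these values. Without that step, ERCC scaling kept 9039 of the 15119 calls at 0 h in call and direction. The 3003 values include the fits with 1 library left out, which keep a nearly identical file. Bounds are given for genes at 0 counts, and the cause of these 0 counts was not tested. Cases of a gene lost in a file numbered 234 in WT at 5 h and 51 in WT at 3 h. Total counts were lower at 3 h, but immunoglobulin genes took 55.1% of gene counts in WT at 3 h and 66.5% at 5 h. Total counts therefore do not measure the depth left for other genes, and whether that depth orders these losses was not tested. The spread between separately sorted samples was not measured by any fit. With files summed, the residual also holds departures from straight lines or, for the mean, changes of the genotype difference between times.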

Other observations

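The tests on spike-in counts and plasma cell genes in this part were chosen after the values were seen, and the swaps of genotype labels before.

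Counts of genes other than immunoglobulin fell per ERCC count in both genotypes after actinomycin D, to 0.461, 0.376 and 0.248 of the 0 h value at 1, 3 and 5 h in WT and to 0.370, 0.273 and 0.182 in the libraries labelled Nat10-deficient. Immunoglobulin counts per ERCC count went to 4.37, 11.3 and 12.1 times the 0 h value in WT and to 0.536, 1.37 and 0.110 in the libraries labelled Nat10-deficient. Several plasma cell genes rose with the immunoglobulin share: Derl3, of the pathway that clears misfolded proteins, went from 17.5 to 792 CPM of other counts in WT, and Slamf7, a plasma cell surface gene, from 28.5 to 509. Others did not: in WT Cd38 stood at 53 at 0 h and 52.8 at 5 h, Irf4 at 173 at 1 h and 53.9 at 5 h, and over the 8 summed libraries Prdm1 had a rho of 0.619 with the share. In the libraries labelled Nat10-deficient Sdc1 stood at 143, 192, 458 and 33.9.

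Gene counts per ERCC count were 33.2 to 55.0 in WT libraries and 772 to 4522 in the libraries labelled Nat10-deficient. The labels state equal amounts of spike-in, and the amounts of total RNA are not given in the sources used here. Comparisons between genotypes on this scale are not read as differences per cell.

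For the mean of the 4 times, 1 of 100 splits that swap genotype labels within times, the real one, gave as many genes as 13346, and the highest of the others was 7803. Each of the other 99 parts at least 2 pairs of nearly identical files, which lowers its count by design, so these splits do not decide on chance. In swaps that keep the files of a group together, 1 of 8 gave as many, the highest of the others 12860 against 13346, and 8 swaps are too few for a share under 0.05.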
